A study of Mus musculus with 10 samples.

How the data were processed

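DNA methylation was measured by reduced representation bisulfite sequencing (RRBS), which cuts DNA with MspI and reads CpG-rich fragments after bisulfite treatment. Bisulfite treatment leaves both 5-methylcytosine and 5-hydroxymethylcytosine unconverted, so the values hold the sum of both marks. Per the labels, the 10 libraries fall into 5 groups of 2 biological duplicates: CAST/EiJ sperm, wild-type (WT) zygotes, CKO zygotes, WT blastocysts and CKO blastocysts. CKO is the name the labels give to embryos of the genotype maternal Tet3 knockout. Embryos came from C57BL/6J eggs fertilised in vitro with CAST/EiJ sperm. Zygotes were collected at 13 h and blastocysts at 96 h after fertilisation, with 40 to 50 zygotes or 4 blastocysts in a library.

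The deposited files give, for each cytosine position, a percent methylation and the methylated and unmethylated read counts from which the authors computed that percent. The percent column equalled the value recomputed from the deposited counts, within 0.001 points, at 100% of the positions of each library. The submitters' processing notes name Bismark 0.10.1, Trim Galore and the genome build mm9. The version of Trim Galore and the settings of either tool are not given in the sources used here. Whether reads were assigned to a parental allele is also not given there. Only the counts were tested. Coordinates are those of the deposited files (mm9), counted from 1. The gene table at hand describes another build (GRCm38). No tile was therefore assigned to a gene, exon, intron or promoter, and the promoter lists drawn up beforehand and Tet3 itself were not analysed.

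The total count per library ranged from 1005492 to 2535229 over 147001 to 218633 positions, with a median of 4 to 9 counts per position. Counts were summed over 100-bp tiles, and a tile or position was used only with at least 10 counts in every library of a fit, on autosomes. This left 7546 tiles and 2737 positions over the 8 embryo libraries, and 7505 tiles and 2713 positions over all 10. The median count per tested tile and library was 38, summed over a median of 4 cytosine positions. Reads carry no molecular identifiers and few genome copies entered each library, so binomial intervals and upper limits cover counting error only. Neighbouring positions can be covered by the same reads, and a tile or window total counts such a read at each position. Tile counts, the minimum of 10 among them, are therefore not numbers of reads. Intervals and limits over a window treat these counts as independent, so they can be too narrow. The 95% intervals are exact Clopper-Pearson intervals, and the upper limit of a share of 0 is 3 counts of the total.

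Tiles were tested with edgeR 4.0.16 (R 4.3.3) by the quasi-likelihood F-test on methylated and unmethylated counts, with a depth term for each library, and Benjamini-Hochberg adjustment at a threshold of 0.05. The 5 embryo comparisons shared a fit of 8 libraries, and WT zygotes against sperm used all 10. The design written before the data were examined left open how edgeR's negative binomial dispersion is set. It was set to 0, which makes the test a quasi-binomial logistic model. That choice was made after a test on simulated data and after the numbers of passing tiles under 4 methods had been seen on the real data. With a dispersion common to all tiles, the same test called 0 tiles in each of the 6 comparisons, the WT zygotes against sperm included. The between-library variance was a median of 8.58 times the binomial variance in the 8-library fit and 6.56 times in the 10-library fit.

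The tile test was run on simulated counts at the real coverages of the CKO and WT zygote comparison, with 200 of 7546 tiles changed. It recovered 9% of the tiles changed by 40 points and 15% of those changed by 60 points, and 3 of its 27 calls were false (11.1%). In the comparison without any simulated change, 1.86% of tiles had an unadjusted p below 0.05. The simulated spread was set to a correlation of 0.2 only after a first setting of 0.02 had given less spread than the real tiles. At that first setting, 3% of changes of 20 points and 22% of changes of 30 points were recovered, against 0% and 1% with the common dispersion. At both settings the changed tiles were drawn from those with a low zygote level. For such changes the power to call single tiles was therefore low. Power for sperm-methylated tiles, which on average start from a higher level, was not simulated separately.

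Windows of 5 Mb were added after the tile test had called no tile between genotypes, so this test was not planned. Each window sums the counts of the positions with at least 5 counts in each sperm replicate and a pooled sperm methylation of at least 80%, and needs at least 100 counts in every embryo library. The positions were chosen on sperm alone. The same edgeR test was used, and 2-Mb and 10-Mb windows were run afterwards. On simulated counts for the zygote comparison, with 200 of 417 windows raised by 10 points, 17.5% were recovered and 2 of 37 calls were false (5.41%). In the simulated blastocyst comparison, where no window was changed, 6.24% of windows had an unadjusted p below 0.05. Windows of the same library are not independent, since a shift of a whole library moves all of them.

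Mean methylation was taken per library over positions, each weighted equally, and compared by an exact two-sided permutation test of the library means. With 2 libraries against 2, the smallest p is 0.333, so no p below 0.05 can be reached there. Positions were sorted by sperm alone into methylated (at least 80% in both replicates), unmethylated (at most 20% in both) and intermediate. Positions unmethylated in sperm with at least 25% in the mean of the 4 zygote libraries formed a further class. Replicates within a group differed, with a chi-square of 6.62 to 13.0 per degree of freedom over tile counts, so none was treated as a repeat deposit. Tile counts hold a read at each position it covers, so this value cannot be read as spread beyond sampling noise.

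The 15 windows of imprinting control regions were recalled from textbook knowledge as mm9 positions before the data were examined and were not checked against an annotation. The tiles named in the text follow a rule set at the same time: up to 5 rising and 5 falling tiles by size among those that passed and whose replicates did not overlap, at least 10 kb apart, or the 3 with the smallest p where none passed. The text gives a part of them. Alternatives were count minimums of 5 and 20, 500-bp tiles, single positions, edgeR's likelihood ratio test, limma 3.58.1 on log2 ratios (1 added to each count), Fisher's exact test on pooled replicates, counts scaled down to at most 50, the deepest 0.1% left out, the X chromosome included, only the 2 groups compared, a replicate block, each library left out in turn, and other sperm bounds. A dispersion common to all tiles and tiles with at least 8 methylated and 8 unmethylated counts were added after the data were seen. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.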

Results

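Methylation was profiled by RRBS in sperm of the CAST/EiJ mouse strain and in WT and CKO embryos at the zygote and blastocyst stages, with 2 libraries in each of the 5 groups. Tet3 encodes a dioxygenase that oxidises 5-methylcytosine and is supplied by the egg to the early embryo. CKO embryos lack the maternal supply by their labels. Sperm libraries held 2535229 and 2315949 counts, zygote libraries 1233982 to 1508297, and blastocyst libraries 1005492 to 1093843.

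The imprinting control regions, which keep the methylation of a single parent, were examined first to see which parental allele the embryo files hold. Regions known to be methylated on the maternal allele, except Snrpn, were nearly unmethylated in the embryos. At Kcnq1ot1, 0 of 371 zygote counts and 0 of 126 blastocyst counts were methylated. Taken as independent, these counts would allow up to 0.809% and 2.38%. Each of the 7 positions there had 53 zygote and 18 blastocyst counts, probably the same reads, so the limits are likely too low. At Igf2r/Airn, 1 of 495 zygote counts and 0 of 240 blastocyst counts were methylated. The second would allow up to 1.25% on the same assumption, with 48 blastocyst counts at each of its 5 positions. Grb10 had 0 of 315 and 0 of 247, Plagl1 0 of 96 and 0 of 50, and Zrsr1 1 of 175 and 0 of 102. The paternally methylated H19/Igf2 region had 8 of 8 and 8 of 12 counts methylated in the sperm replicates and 76 of 76 in zygotes. Blastocyst counts there came from 1 WT library (10 of 10) and 1 CKO library (1 of 2). The paternally methylated Dlk1-Gtl2 region, which had too few counts for the test, differed between groups in both directions. Methylated counts there were 16 of 16 and 10 of 10 in the WT zygote libraries and 7 of 13 and 1 of 2 in the CKO zygote libraries. They were 2 of 5 and 0 of 9 in the WT blastocyst libraries and 5 of 5 and 4 of 4 in the CKO blastocyst libraries. Sperm had 0 of 252 at Kcnq1ot1 and 1 of 190 at Igf2r/Airn, and 16 of 125 at Zrsr1. At Grb10 it had 0 of 148 in replicate 1 and 25 of 98 in replicate 2. The labels do not say whether reads were selected by allele.

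Snrpn was the exception among the maternally methylated regions with counts in zygotes and blastocysts. Over positions 67149466 to 67150115 of chromosome 7, methylation was 0 of 356 counts in sperm, 22.4% of 389 in zygotes (95% interval 18.3 to 26.8) and 19.2% of 490 in blastocysts (15.8 to 22.9). Nearly all of it lay at positions 67149489 (39.5% of 114 zygote counts) and 67149537 (36.8% of 114), while the adjacent position 67149488 had 0 of 46. The intervals treat counts of neighbouring positions as independent and can be too narrow. Of the 15 windows, 10 had any count and 2 (Snrpn and Igf2r/Airn) had enough for the test, and neither passed for any of the 5 embryo comparisons, whether adjusted over the list alone or over all tiles and regions (edgeR). The count was also 0 at an unadjusted p below 0.05 and 0 with limma. The mean of those 2 windows was 10.6% in CKO and 11.8% in WT zygotes, a difference of -1.21 ± 6.19 points (SD), and 10.8% against 7.66% in blastocysts, a difference of 3.11 ± 0.391 points. The exact two-sided permutation p was 1 and 0.333, the second being the smallest that 2 against 2 libraries can give.

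The comparison of CKO with WT zygotes asks whether methylation of the fertilised egg differs without maternal Tet3. CKO zygotes were more methylated at positions that sperm had methylated. Over 989 such positions, methylation was 96.8% ± 0.0808 (SD, n = 2) in sperm, 58.5% ± 0.158 (n = 2) in WT zygotes and 68.5% ± 0.169 (n = 2) in CKO zygotes. The difference of 10.0 points was larger than the spread between replicates (SD of the difference 0.231), and the lower CKO library lay 9.77 points above the higher WT library. Positions unmethylated in sperm stayed low, at 1.79% ± 0.0502 (n = 2) in WT and 2.13% ± 0.304 (n = 2) in CKO zygotes over 1510 positions. At the 214 intermediate positions the levels were 25.3% ± 1.498 and 36.3% ± 2.18 (n = 2 each). Over all 2737 positions, WT zygotes averaged 24.4% ± 0.0632 and CKO zygotes 29.2% ± 0.500 (n = 2 each), a difference of 4.82 points. For these differences the exact two-sided permutation p was 0.333, the smallest possible. At a count minimum of 20 only 11 sperm-methylated positions remained, and there the difference was -4.64 points.

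**Figure D1:**
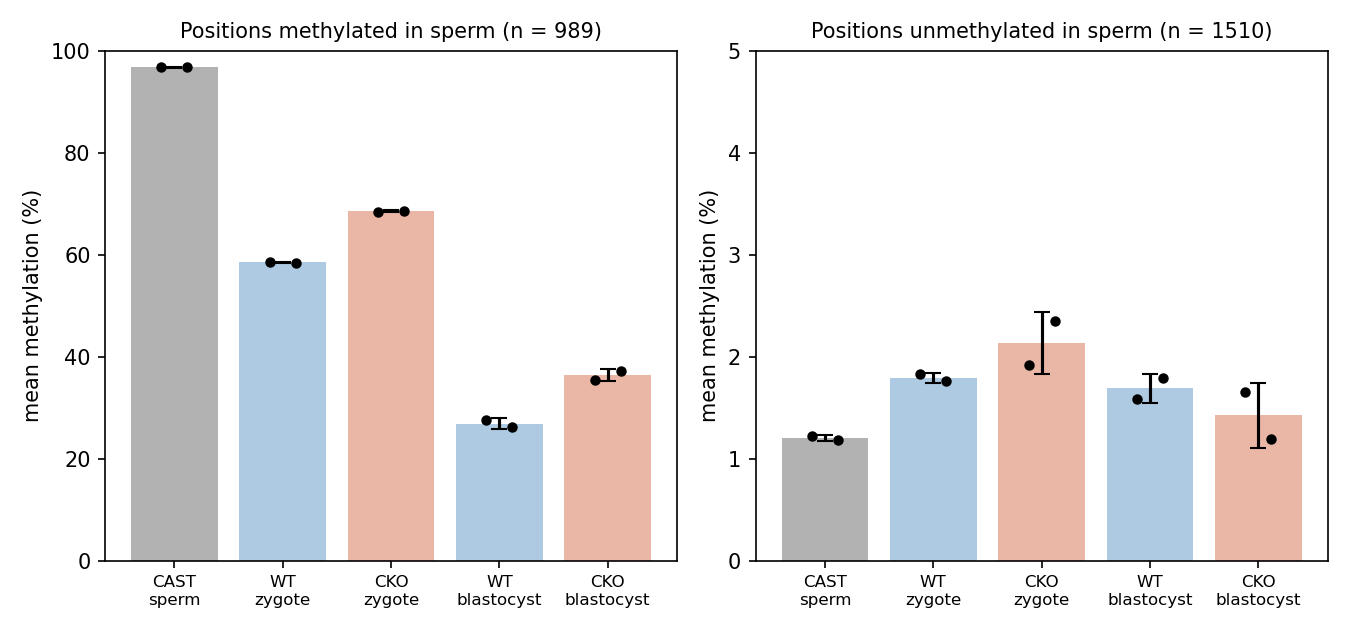
Mean methylation (%) per group over positions methylated in sperm (left, 989 positions, axis 0 to 100) and unmethylated in sperm (right, 1510 positions, axis 0 to 5). Bars are means of 2 libraries, error bars are SD and points are libraries: on the left CKO lies above WT at both stages (68.5% against 58.5% in zygotes, 36.3% against 26.9% in blastocysts), while on the right every group lies below 2.5%.

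The share of sperm-methylated positions at 20% or less was 10.9% ± 0.929 in WT and 4.15% ± 0.858 in CKO zygotes (SD, n = 2 each), and the share at 80% or more was 26.9% ± 1.72 and 38.0% ± 2.00. CKO exceeded WT on all 19 autosomes, by 1.47 to 19.04 points. The difference was 11.3 points in tiles with at most 3 cytosine positions (1542 tiles), 12.3 points in tiles with 4 to 7 (316 tiles) and 13.4 points in tiles with at least 8 (23 tiles).

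No tile passed between CKO and WT zygotes. The edgeR quasi-likelihood test called 0 of 7546 tiles, with 306 at an unadjusted p below 0.05, of which 261 were higher and 45 lower in CKO. edgeR's likelihood ratio test called 3, limma 0, and Fisher's exact test on pooled replicates, which ignores the spread between replicates, 1597. The tile with the smallest p lay on chromosome 12 at positions 107211901 to 107212000, with an adjusted p of 0.0973 in edgeR. It had 0% in both WT libraries (96 and 64 counts summed over 4 positions). In the CKO libraries it had 65.0% and 57.6% (40 and 132 counts). In 5-Mb windows of sperm-methylated positions, a test added after this result, 256 of 417 windows were higher in CKO zygotes and 0 lower (edgeR, adjusted p below 0.05). The window difference was above 0 in 404 of 417 windows, with a median of 11.2 points. The count was 153 without WT zygote replicate 1.

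The same genotype comparison at the blastocyst stage asks whether a difference is still present after cleavage. CKO blastocysts were more methylated than WT blastocysts at sperm-methylated positions, with 36.3% ± 1.20 against 26.9% ± 1.02 (SD, n = 2 each). The difference of 9.47 points exceeded the spread between replicates (SD of the difference 1.58), and the lower CKO library lay 7.89 points above the higher WT library. At sperm-unmethylated positions the levels were 1.42% ± 0.320 in CKO and 1.69% ± 0.142 in WT (n = 2 each), a difference of -0.266 points that is smaller than its SD of 0.350. Over all positions CKO averaged 15.6% ± 0.268 and WT 11.8% ± 0.180 (n = 2 each), a difference of 3.83 points. The exact two-sided permutation p was 0.333, the smallest possible, for the sperm-methylated positions and for all positions, and 0.667 for the sperm-unmethylated positions. CKO exceeded WT on all 19 autosomes, by 2.53 to 14.9 points. In the 23 CpG-dense sperm-methylated tiles the difference was 19.01 points, against 7.90 points in the 316 tiles with 4 to 7 positions and 9.22 points in the 1542 sparse ones.

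The edgeR quasi-likelihood test called 0 of 7546 tiles between CKO and WT blastocysts, with 205 at an unadjusted p below 0.05 (172 higher, 33 lower). The likelihood ratio test and limma called 0 as well, and Fisher's exact test on pooled replicates 1281. The tile with the smallest p lay on chromosome 5 at positions 107621501 to 107621600, with 63.0% ± 1.53 in CKO and 2.32% ± 3.27 in WT blastocysts (SD, n = 2 each) and an adjusted p of 0.531 in edgeR. Of the 417 windows, 133 were higher in CKO blastocysts and 0 lower, and the difference was above 0 in 390, with a median of 9.26 points. This count was 65 with limma, and 80, 61, 67 and 86 without WT blastocyst replicate 1, WT replicate 2, CKO replicate 1 and CKO replicate 2.

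**Figure D2:**
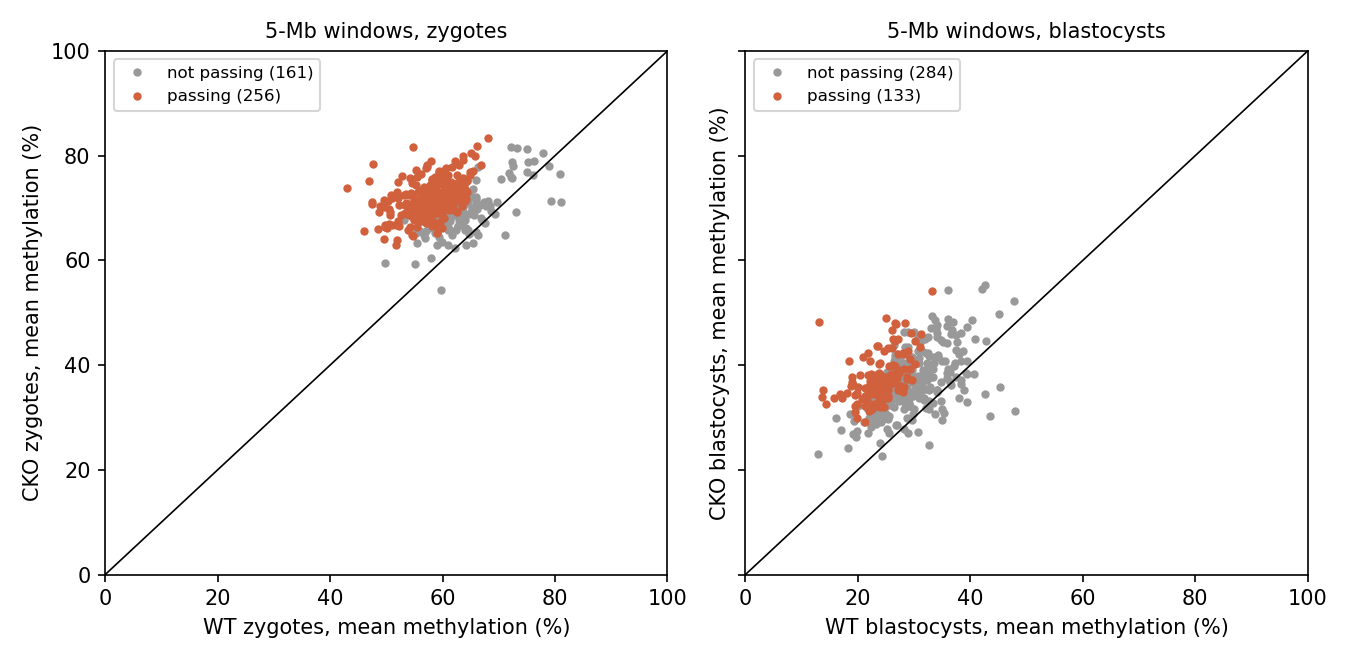
Mean methylation (%) at sperm-methylated positions in 417 windows of 5 Mb, CKO (vertical axis) against WT (horizontal axis), in zygotes (left) and blastocysts (right). Each point is a window (mean of 2 libraries), the line marks equal values, and coloured windows passed the edgeR test: 256 in zygotes and 133 in blastocysts, with 404 and 390 windows above the line.

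The interaction asks whether the genotype difference itself changed between the stages. At sperm-methylated positions it was 10.0 points in zygotes and 9.47 points in blastocysts, a change of -0.535 ± 1.13 points (SE), which is smaller than its error and was not tested by permutation. On larger sets the difference was smaller in blastocysts by more than the error, with a change of -3.26 ± 0.904 points (SE) over 5438 positions at a count minimum of 5 and -2.38 ± 0.795 points over 1881 tiles. In the 23 of these tiles with at least 8 cytosine positions, the change went the other way, at 5.65 ± 2.07 points (SE). Averaged over both stages, CKO exceeded WT by 9.74 points, with an exact permutation p of 0.0556 (two-sided, genotype permuted within stage, 36 arrangements), the smallest these arrangements allow. The edgeR test of the interaction called 0 of 417 windows, with 31 at an unadjusted p below 0.05, and limma called 0. It called 1 of 7546 tiles, with 167 at an unadjusted p below 0.05. This was the chromosome 12 tile at positions 107211901 to 107212000. It had 0% in WT zygotes, 61.3% ± 5.25 in CKO zygotes, 55.0% ± 1.03 in WT blastocysts and 3.75% ± 5.30 in CKO blastocysts (SD, n = 2 each). The genotype difference fell by 112.6 points between stages (edgeR, adjusted p = 0.000427). limma called no tile here, and the call was lost without WT blastocyst replicate 2 and without CKO blastocyst replicate 2.

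Between the zygote and the blastocyst, methylation of sperm-methylated positions fell in both genotypes. WT embryos lost 31.7 points and CKO embryos 32.2 points, leaving 45.9% ± 1.24 (SE) and 53.0% ± 1.24 of the zygote level. The retained share was 7.11 ± 1.76 points (SE) higher in CKO, a difference that was larger than its error and was not tested on these means. Relative to sperm, WT zygotes held 60.4% ± 0.121 and CKO zygotes 70.8% ± 0.130 of the level (SE), and WT and CKO blastocysts 27.8% ± 0.748 and 37.5% ± 0.878. The fall averaged over genotypes was -31.9 points, at the smallest permutation p allowed (exact, two-sided, 0.0556). In the windows, 414 of 417 were lower in WT blastocysts and 416 of 417 in CKO blastocysts, and none was higher. Only 3 of 1881 sperm-methylated tiles kept at least 60% in each of the 4 blastocyst libraries.

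Among single tiles, 31 fell and 1 rose in WT, and 54 fell and 1 rose in CKO (edgeR, adjusted p below 0.05). The 1 rise in CKO is by the sign of the fitted odds ratio, and its difference of means did not reach 20 points. A tile on chromosome 17 at positions 43214201 to 43214300 fell from 92.4% ± 0.606 in WT zygotes to 5.43% ± 0.238 in WT blastocysts (SD, n = 2 each, adjusted p = 4.79e-05). A tile on chromosome 9 at positions 7961401 to 7961500 fell from 100% in both CKO zygote libraries to 7.67% ± 2.01 in CKO blastocysts (adjusted p = 0.00153). The tile that rose in WT was the chromosome 12 tile at positions 107211901 to 107212000. These counts depend on the test: the likelihood ratio test called 179 and 154, and limma 0 and 5. In WT the count was 3 without WT zygote replicate 1 and 1 without WT blastocyst replicate 1 or replicate 2. In CKO it was 1 and 5 without CKO blastocyst replicates 1 and 2, 24 and 15 without CKO zygote replicates 1 and 2, 21 and 17 without WT blastocyst replicates 1 and 2, and 86 without WT zygote replicate 2.

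WT zygotes were compared with sperm, the father's gamete. What this comparison measures depends on whether the embryo files hold 1 or both parental alleles, which is not given. If maternal reads are present, a lower or higher tile can also come from the allele of the C57BL/6J egg. Of 7505 tiles, 1034 were lower and 105 higher in WT zygotes (edgeR, adjusted p below 0.05), of which 1022 and 81 moved by at least 20 points. On chromosome 9 at positions 121693001 to 121693100, methylation was 98.9% ± 1.57 in sperm (SD, n = 2). It was 0% in both WT zygote libraries (21 and 18 counts summed over 3 positions), with an adjusted p of 0.000196 in edgeR. On chromosome 5 at positions 147050001 to 147050100 methylation was 97.9% ± 2.95 in sperm and 0% in WT zygotes (40 and 10 counts summed over 2 positions). The tiles that rose included chromosome 8 at positions 25706001 to 25706100, with 1.35% ± 1.91 in sperm and 95.3% ± 2.35 in WT zygotes (adjusted p = 4.80e-13), and chromosome 18 at positions 36038701 to 36038800, with 1.28% ± 1.81 and 79.7% ± 5.74 (adjusted p = 2.06e-10). Those tiles held 56.1% ± 34.5 and 12.1% ± 17.2 in WT blastocysts. The count of passing tiles was 136 without sperm replicate 1, 191 without sperm replicate 2 and 687 without WT zygote replicate 1.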

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

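The tests of explanations in this part were chosen after the genotype difference was seen, and only for the comparison of low and high tiles was the prediction written before its result was known. The interaction test was planned. The tile on chromosome 12 at positions 107211901 to 107212000 stood out because its genotype difference changed between the stages (interaction test). The change was -112.6 points, from 0% in WT and 61.3% in CKO zygotes to 55.0% in WT and 3.75% in CKO blastocysts. The tile holds 4 cytosine positions and 40 to 132 counts per library. These counts are summed over the positions, which the same reads can cover, so the number of reads is likely lower.

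For the higher methylation of CKO embryos at sperm-methylated positions, incomplete bisulfite conversion would need 24.1% unconverted reads in CKO zygotes and 12.9% in CKO blastocysts, while CKO minus WT at sperm-unmethylated positions was 0.336 points in zygotes and -0.266 points in blastocysts, which argues against it at both stages. Sperm left among the embryos would need 26.1% of zygote reads and should lower positions that only embryos had methylated by about -9.65 points, but CKO zygotes lay 2.22 points above WT there (182 positions, SD of the difference 1.66). Those positions were picked on the mean of the same zygote libraries, which can raise their level, so the expected fall may be overstated. In blastocysts the same test gave -3.37 points (SD 1.87) where 13.5% sperm would give -2.37, so sperm stays open there as a candidate explanation, beside the difference in maternal Tet3, which is open at both stages. In tiles picked on 1 WT replicate and read against the other, CKO minus WT in low tiles exceeded that in high tiles by 4.09 points in zygotes (95% bootstrap interval -0.717 to 8.47) and by 11.6 points in blastocysts (8.33 to 14.8). In zygotes CKO minus WT was 14.4 points in low tiles and 10.3 points in high tiles, where sperm alone would give 13.3 and 10.5. Unlike the 182 positions, this comparison leaves sperm open in zygotes as well. In blastocysts CKO minus WT was 13.4 points in low tiles and 1.79 points in high tiles, where sperm alone would give 10.3 and 7.33. The high tiles go against sperm as the whole cause, and a part from sperm stays open. The sperm values use the share of sperm reads needed in tiles (30.0% in zygotes, 13.1% in blastocysts), so their size is set by the rise itself. A CKO loss of sperm methylation smaller by the same share in every tile would give the same values. The direction therefore cannot single out sperm.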

How the results depend on the processing

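The common dispersion, the informative tiles, every window test and the alternatives for the change between stages were chosen after the data were seen. CKO lay above WT at sperm-methylated positions at both stages under every alternative run except the count minimum of 20 in zygotes. The tile counts depended on the test and on single libraries, and the minimum of 20 left few positions for the means. Causes were not tested except where fewer positions, tiles, windows or libraries follow from the alternative itself. The promoter lists and their widths were not run, and the minimum of 20 left no position for the class unmethylated in sperm and methylated in zygotes.

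At a minimum of 20, CKO minus WT at 11 sperm-methylated positions was -4.64 points in zygotes (reversed) and 2.64 in blastocysts, against 10.0 and 9.47 at 989 positions. At 38 positions of any kind it was 1.01 and 3.08, and at 22 sperm-unmethylated positions 1.22 and 2.57, the last reversed from -0.266. At a minimum of 5 it was 12.2 points in zygotes and 8.94 in blastocysts over 5438 sperm-methylated positions, and 100-bp tiles gave 11.5 and 9.12. Weighting by reads gave 9.47 in zygotes, and a sperm bound of 60% gave 10.5. The change between stages, -0.535 points, was -3.26 at a minimum of 5, 7.27 at 20 (11 positions, SE 5.20) and -2.38 over tiles, and ranged from -1.38 to 0.315 with a library left out. Over all tiles, whatever their sperm methylation, CKO minus WT was 4.22 points in zygotes and 2.85 points in blastocysts. At positions unmethylated in sperm and methylated in zygotes, the differences of 17.6 and -8.25 points (24 positions) were 2.22 and -3.37 at a minimum of 5 (182 positions) and 2.49 and -0.845 over tiles. A sperm bound of 10% gave -1.73 in blastocysts.

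Tiles between CKO and WT zygotes numbered 0, but 1 at a minimum of 20, 3 with 500-bp tiles, 3 by the likelihood ratio test and 1597 by Fisher's test, which also called 1281 in blastocysts. The interaction tile was lost with single positions (0), limma (0) and the common dispersion (0). Blastocyst against zygote tiles in WT, 32, were 52 with 500-bp tiles, 0 with single positions, 179 by the likelihood ratio test, 0 with limma, 2257 by Fisher's test, 18 with counts scaled down to 50, 16 with only the compared groups and 0 with the common dispersion. In CKO the 55 tiles became 31 at a minimum of 20, then 127, 0, 154, 5, 2379, 32 and 0 for 500-bp tiles, single positions, the likelihood ratio test, limma, Fisher's test, only the compared groups and the common dispersion. WT zygotes against sperm, 1139, became 1998 and 331 at minimums of 5 and 20, 328 with single positions, 2929 by Fisher's test and 0 with the common dispersion.

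Windows higher in CKO numbered 256 of 417 in zygotes and 133 in blastocysts, against 269 and 101 of 669 (2 Mb), 182 and 128 of 248 (10 Mb), and 175 and 65 with limma. Blastocyst against zygote windows were 657 of 669 (2 Mb) and 247 of 248 (10 Mb) in WT, and 665 and 248 in CKO. The other 2 ways to pair off the 4 libraries of a stage passed 0 windows, which are too few ways for a share under 0.05. Differences between replicates in single tiles did not go together between groups (correlations of deviations -0.0380 to 0.0300). A shift shared by whole libraries would not show there, so pairing by replicate number is not excluded. A replicate block gave 14 WT and 27 CKO blastocyst against zygote tiles and 3 interaction windows.

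Leaving out each library in turn, with the lone sample assumed to vary like the other groups, gave 0 to 1 tiles between zygotes, 0 to 0 between blastocysts, 0 to 1 for the interaction, 1 to 32 and 1 to 86 for blastocyst against zygote in WT and CKO, and 136 to 1208 for WT zygotes against sperm. The 1 zygote tile appeared without WT zygote replicate 2. Windows ranged from 153 to 252 in zygotes (1 of 185 lower in CKO without CKO zygote replicate 2), 61 to 140 in blastocysts, 0 to 0 for the interaction, and 401 to 416 and 404 to 417 for stage in WT and CKO. CKO minus WT ranged from 9.88 to 10.1 and 8.62 to 10.3 points at sperm-methylated positions in zygotes and blastocysts, 4.47 to 5.18 and 3.64 to 4.02 at all positions, 0.121 to 0.552 and -0.492 to -0.0396 at sperm-unmethylated positions, and 13.3 to 21.9 and -11.3 to -5.23 at those methylated in zygotes. Over the tiles chosen by the rule, no direction reversed. With a library left out, 192 results stayed on their side of the threshold, 51 lost and 1 gained the call, and under the other alternatives 270 stayed, 38 lost and 8 gained it.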

Other observations

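The tests in this part were chosen after the results were seen. A small set of positions was unmethylated in sperm but methylated in zygotes. At a count minimum of 5 there were 182 of them, with 3.21% ± 0.0904 in sperm, 40.1% ± 0.475 in WT zygotes, 42.4% ± 1.59 in CKO zygotes, 20.7% ± 1.30 in WT blastocysts and 17.3% ± 1.35 in CKO blastocysts (SD, n = 2 each). At the minimum of 10 used elsewhere there were 24, with 29.0% ± 1.19 in WT zygotes, 46.6% ± 6.12 in CKO zygotes, 31.9% ± 1.20 in WT blastocysts and 23.6% ± 4.28 in CKO blastocysts, so there the blastocyst level was lower in CKO but not in WT. The positions were picked on the zygote level. Maternal reads added at these positions alone would need 1.70 times as many counts there, but zygote counts per sperm count were 1.01 times those at other sperm-unmethylated positions (95% bootstrap interval 0.975 to 1.08), which argues against that. Maternal reads throughout the files would leave this ratio near 1, but the maternally methylated Kcnq1ot1 window had 0 of 371 zygote counts methylated (53 at each of its 7 positions). Repeated reads of a single strand would leave the other strand of the same CpG at background. Yet that strand lay 24.2 points above other sperm-unmethylated CpGs (130 picked strands, 95% bootstrap interval 20.3 to 28.4), which argues against that too. Both strands of a double-stranded fragment can be read, so this cannot exclude repeated reads of few fragments. The maternally methylated Snrpn window was likewise 0 of 356 in sperm with 39.5% and 36.8% at 2 positions in zygotes, but there the other strand of the first CpG had 0 of 46 zygote counts against 45 of 114. Maternal reads that replace CAST reads were not tested, so maternal reads stay open, beside methylation gained on the paternal copies.

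X-chromosome counts were fewer in blastocysts. They made up 0.525% ± 0.0339 of counts in the 4 blastocyst libraries and 0.985% ± 0.0984 in the 4 zygote libraries (SD), against 0.928% in sperm, with an exact two-sided permutation p of 0.0286 for zygotes against blastocysts, the smallest that 4 against 4 allows. Methylation-dependent recovery of fragments would leave no difference within sperm-unmethylated positions, but the blastocyst to zygote ratio of X shares was 0.540 there. If the embryo reads are paternal alone, which the labels do not state, the blastocyst share would correspond to 4.53 female embryos among 16. Chance sex of the embryos cannot be told apart from other causes, since under that assumption the binomial probability of as few is 0.0384 for 4 and 0.105 for 5. No biological explanation was tested.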
